A study of Danio rerio with 8 samples.

How the data were processed

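Expression was measured on an Affymetrix zebrafish array in 8 samples of heart ventricle from Danio rerio, 4 control and 4 resected. Per the labels, each sample was a pool of 50 ventricles collected 2 weeks after the operation. Total RNA was isolated with Trizol, and biotin-labelled target was prepared with an amplification kit, per the labels' protocols. The series is described as having 4 biological replicates in each of its 2 conditions. What was done to the control animals is not given in the sources used here.

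The deposited values are on a log2 scale. The submitters' processing notes name affy and RMA, a method of background correction, quantile normalization and probe summarisation, without versions. The table held 15617 probe sets. The array medians lay between 5.78 and 5.82, and the values between 2.01 and 14.64. RMA values carry no detection call, so a low value is not a measure of absence, and the number of arrays limits the precision. The column of every array was matched to its sample by the sample's label, and 0 columns were left unused.

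The 115 control probe sets of the manufacturer were left out of the tests, which left 15502. Gene symbols came from the platform annotation and were brought up to date through a gene table of the GRCz12tu assembly. A single symbol was found for 10795 probe sets, several for 135 and none for 4572. Entrez identifiers matched the gene table for 10711 probe sets and not for 84, and 1 symbol was replaced. No coordinates are given, because the build behind the array design is not named. The 8793 genes were each represented by the probe set with the highest mean over all arrays; 1539 genes had more than 1 probe set. Among changed genes, 114 had several probe sets. All of these went the same way for 97 genes, and 0 genes had a probe set that changed in the opposite direction. Array probes can also bind close paralogs, so the globins, the contractile protein families and other multigene families are uncertain as to the copy measured.

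Resected and control arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), two-sided, without a replicate term, and p-values were adjusted by Benjamini-Hochberg over all 15502 probe sets. The threshold was an adjusted p of 0.05. The value of a gene's change is the resected mean minus the control mean in log2 units, with the standard error (SE) of the fit. In all, 25 gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists, with an estimated correlation and with fry as alternatives. Lists needed 3 measured members. The difference between 3' and 5' probe sets of the actin and GAPDH control transcripts was taken as a sign of RNA quality and compared by an exact two-sided permutation test. Groups, tests, lists and the rule for the named genes were fixed before the data were examined.

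The named genes are the 12 largest increases and the 12 largest decreases among genes past the threshold whose 4 resected values do not overlap the 4 control values. Probe sets that end in _x_at, probe sets with several symbols, and clone or locus names were left out of these largest changes. In the lists, probe sets that end in _x_at were kept, and krt91 rests on one. From each list, up to 4 members past the threshold with the largest change are named, or the 2 with the smallest p where none passed. Every member of a list with 10 or fewer measured members may be named. Genes outside this rule are said to have been chosen after their values were seen.

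The test functions were tested on simulated data with the means and spreads of the 15502 probe sets, in 20 draws of 200 changed probe sets. The test recovered 48.1% of the log2 changes of 0.5, 91.9% of those of 1 and 99.1% of those of 2, and 4.73% of its calls fell on unchanged probe sets. Camera called 20 of 20 lists shifted by 0.3, and 1 of 441 unshifted lists. These simulated genes varied independently, so the simulation does not cover correlated lists. The alternatives tried were a replicate block, a trend or robust variance prior, array weights, further quantile normalization or median centring, filters on dim probe sets, no variance moderation, the mean of a gene's probe sets, other list tests, and leaving out each array. Camera has no robust prior, so with that setting the lists were ranked on the statistics of the fit.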

Results

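Gene expression was measured in zebrafish ventricles 2 weeks after surgery, in 4 pools from control animals and 4 pools from animals with a resected ventricle, each of 50 ventricles. The comparison asks which transcripts differ in the injured heart, which in zebrafish regrows lost muscle. Values are RMA expression on a log2 scale, and changes are given as resected minus control in log2 units, with the standard error of the limma fit and n = 4 arrays per group.

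Transcripts of extracellular matrix proteins rose in resected ventricles. The largest increase among the named genes was in postnb, a periostin secreted by activated fibroblasts, which rose by 3.74 ± 0.12 (SE), or 13.4-fold, from 7.28 ± 0.24 to 11.02 ± 0.08 (SD, n = 4; adjusted p = 1.64e-07, limma). The fibronectin gene fn1a rose 11.1-fold, by 3.48 ± 0.15 (adjusted p = 1.91e-06). Among the 12 largest increases were also the type I collagen chains col1a2 (2.39 ± 0.13) and col1a1a (2.25 ± 0.14), the secreted chaperone clu (2.5 ± 0.17) and the heparin-binding growth factor mdka (2.31 ± 0.14). The others were egln3, a prolyl hydroxylase that acts on hypoxia-inducible factors (2.59 ± 0.43), the receptor kinase musk (2.56 ± 0.27), lgals3bp.1 (2.39 ± 0.35), the haem synthesis enzyme alas2 (2.33 ± 0.30), the calcium buffer pvalb2 (2.32 ± 0.17) and the globin hbba2 (2.29 ± 0.31).

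The 12 largest decreases of the named genes were smaller than the 12 largest increases. The largest decrease was in the prostaglandin D synthase gene ptgdsb.2, 3.85-fold lower in resected ventricles (-1.95 ± 0.34, adjusted p = 0.00749, limma). The insulin-like growth factor binding protein igfbp1b changed by -1.75 ± 0.26, the synaptic vesicle protein gene syt1a by -1.72 ± 0.15 and the transcription factor klf9 by -1.50 ± 0.28. The remaining decreases were in fam184aa (-1.45 ± 0.24), the autophagy kinase ulk1b (-1.42 ± 0.31), gbp (-1.40 ± 0.21), the cell cycle inhibitor cdkn1ca (-1.38 ± 0.22), the chymotrypsinogen ctrb.1 (-1.32 ± 0.18), the mitochondrial ADP/ATP carrier slc25a4 (-1.31 ± 0.28), zdhhc2 (-1.28 ± 0.22) and the HSP90 co-chaperone ahsa1a (-1.27 ± 0.10). The call for ulk1b ended without control replicate 3 or without resected replicate 1 or 3 (adjusted p = 0.0517, 0.0621 and 0.0611). That for slc25a4 ended without control replicate 4 or resected replicate 1, 2 or 3 (0.0611, 0.0514, 0.0559 and 0.0639).

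**Figure D1:**
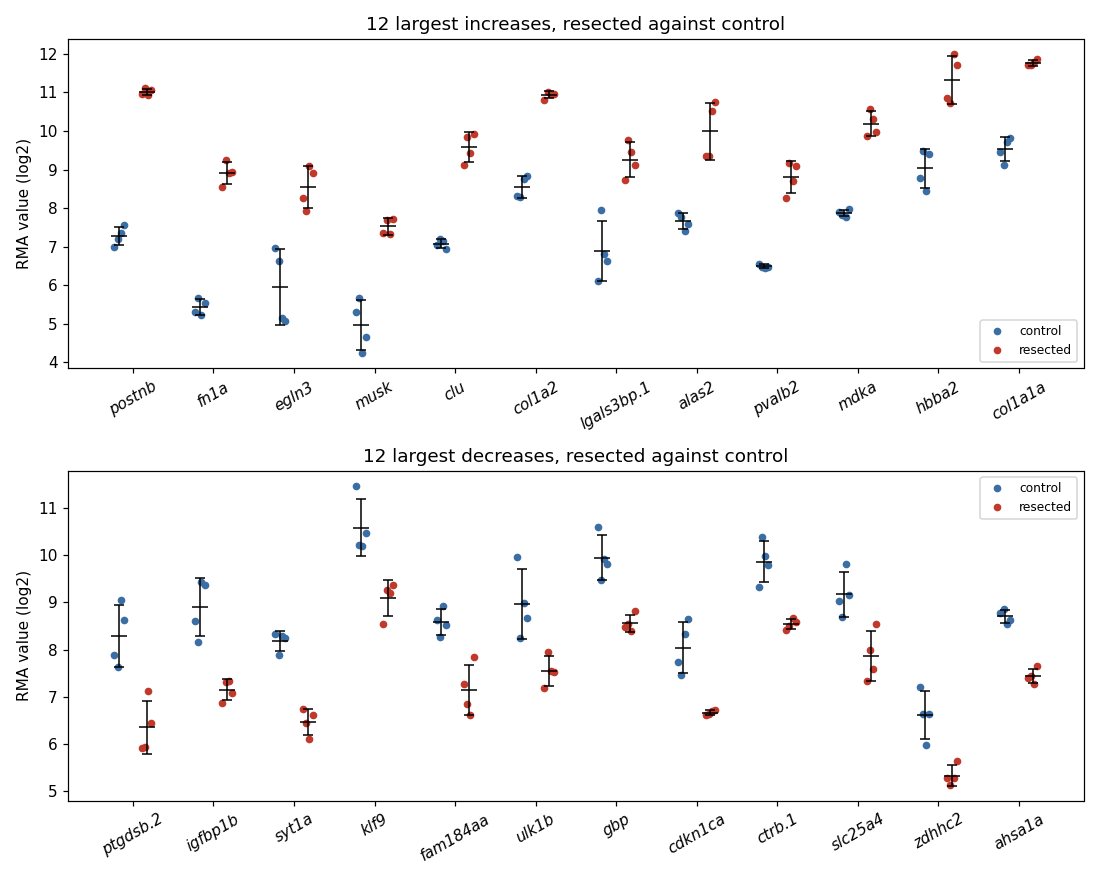
Expression of the 12 genes with the largest increases (top) and the 12 with the largest decreases (bottom); the vertical axis is the RMA value in log2 units, points are single arrays (4 per group), and bars are the mean and SD. For every gene shown the resected arrays lie wholly above or wholly below the control arrays, which was a condition of the choice; postnb averages 7.28 in control and 11.02 in resected arrays.

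In all, 1062 of 15502 probe sets passed the threshold, 664 higher and 398 lower in resected ventricles, and 215 of them changed by 2-fold or more (176 higher, 39 lower). By gene, 708 of 8793 changed, 444 higher and 264 lower. The 4 values of each group did not overlap for 15.7% of the genes, against 2.86% by chance. The number of changed genes was 1083 without control replicate 2, and 433, 371 and 398 without control replicate 4, resected replicate 2 and resected replicate 3, for which 1608, 642, 545 and 604 probe sets changed. The 664 higher probe sets became 409, 394 and 433 without the last 3 of these arrays. The 398 lower ones became 657, 247, 233, 213, 151 and 171 without control replicates 2, 3 and 4 and resected replicates 1, 2 and 3. Without moderation of the variance 201 genes changed.

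Of 47 measured genes of the extracellular matrix and its remodelling, 28 rose and 0 fell (31 and 1 adjusted over the list alone), led by postnb, fn1a, col1a2 and col1a1a. The list stood higher than other genes (camera adjusted p = 7.97e-25), and also with an estimated correlation (adjusted p = 0.00322), the only list of which that was true. Cell cycle and DNA replication genes rose as well: 27 of 75 were higher and 0 lower (37 and 0 adjusted over the list alone), among them thymidylate synthase tyms (1.56 ± 0.12), the replication helicase subunit mcm2 (1.29 ± 0.25) and the mitotic kinase cdk1 (1.27 ± 0.19). For this list camera gave an adjusted p = 2.67e-14, and an adjusted p = 0.193 with an estimated correlation. Control replicate 2 had the highest control mean over its members (0.133 above the control mean, against -0.087 to 0.008), and without that array 32 rose and 0 fell. Smooth muscle and outflow tract genes were higher for 4 of 9 members and lower for 0 (4 and 0 adjusted over the list alone), with tagln at 1.88 ± 0.13 and tagln2 at 0.64 ± 0.11. The smooth muscle actin acta2 was at -0.07 ± 0.15 (adjusted p = 0.81, limma). Camera gave an adjusted p = 0.00395, and an adjusted p = 0.182 with an estimated correlation. That correlation was -0.05, below the preset 0.01. The list median was 0.08 and its mean 0.4, and 3 of its 9 members are also in other lists, the riser tpm1 among them. The call for mylka (0.37 ± 0.09) ended without control replicate 4 or any 1 resected array (adjusted p = 0.0549 to 0.101, limma).

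Of 17 genes listed as markers of the epicardium, the outer cell layer of the heart, 4 rose and 1 fell in whole ventricles (5 and 2 adjusted over the list alone). The list shares 5 genes with other lists, and which cells carried the change was not measured. The retinoic acid synthesis enzyme aldh1a2 rose by 1.1 ± 0.13, the annexin anxa2a by 1.37 ± 0.13 and the keratin krt18a.1 by 0.68 ± 0.11, beside clu. The member that fell, raraa, a retinoic acid receptor named after its value was seen, was at -0.57 ± 0.10. By camera the adjusted p was 0.0142, and the adjusted p was 0.193 with an estimated correlation, which was -0.02 against the preset 0.01. Of 26 endothelial and endocardial genes, cldn5a rose (0.42 ± 0.08) and gata2a fell (-0.44 ± 0.11), with 1 and 1 adjusted over the list alone. Camera gave an adjusted p = 0.954 in the higher direction, beside a median of -0.04 and a mean of 0.01. The level of cldn5a was low, at 3.48 in control and 3.9 in resected arrays, where the array medians lay between 5.78 and 5.82. The call for cldn5a ended without resected replicate 3 (adjusted p = 0.0509) and with the mean of its probe sets (0.191), and that for gata2a when any array but control replicates 2 and 4 was left out (0.0572 to 0.121) or with an intensity trend in the variance prior (0.0525).

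**Figure D2:**
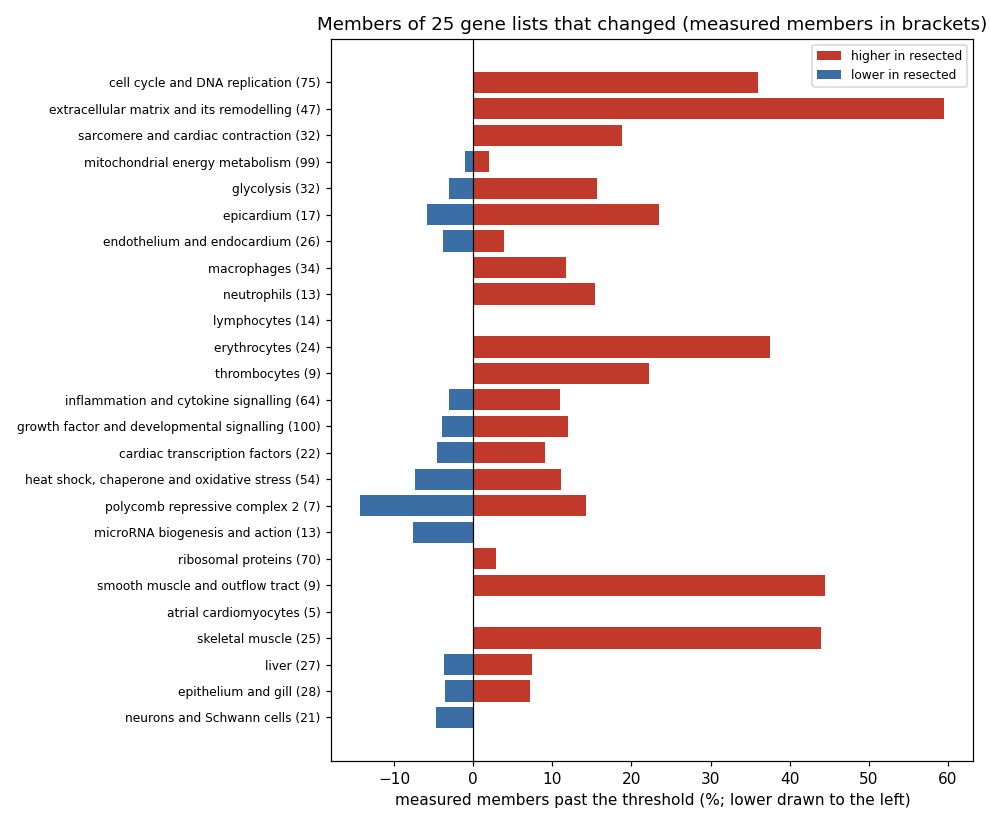
Share of the measured members of each of 25 gene lists that passed the threshold, in percent, with members higher in resected ventricles to the right and members lower in them to the left; the number of measured members is in brackets. The extracellular matrix list has 28 of 47 members higher, and the lymphocyte and atrial lists have none past the threshold.

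The erythrocyte, thrombocyte, macrophage, neutrophil and inflammation lists were called higher in resected ventricles with the preset correlation and none of them with an estimated one (adjusted p = 0.232 or 0.317), and the lymphocyte list was not called. Of 24 erythrocyte genes, 9 rose and 0 fell (15 and 0 adjusted over the list alone): besides alas2 and hbba2, these included the anion exchanger slc4a1a (2.05 ± 0.31) and the carbonic anhydrase cahz (1.89 ± 0.20). With camera the list had an adjusted p = 1.62e-07, and an adjusted p = 0.232 with an estimated correlation. Of 9 thrombocyte genes, fn1b (2.1 ± 0.14) and the clotting factor f13a1b (0.91 ± 0.17) rose and 0 fell (3 and 0 adjusted over the list alone), while the thrombocyte integrin itga2b was at 0.04 ± 0.17. Of these 9 genes 4 are also in other lists, and fn1b and thbs1b (0.35 ± 0.12) are in the matrix list. For this list the adjusted p of camera was 0.0189, an adjusted p = 0.232 with an estimated correlation and 0.0593 without control replicate 3.

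Of 34 macrophage genes, 4 rose and 0 fell over all genes tested, and 25 rose and 2 fell adjusted over the list alone. The NADPH oxidase subunit ncf1 rose by 1.61 ± 0.25, the myeloid transcription factor spi1b by 0.90 ± 0.23, the chemokine receptor cxcr4b by 0.79 ± 0.16 and the receptor csf1ra by 0.52 ± 0.11. Control replicate 2 lay apart from the other control arrays in this list: its mean over the members was 0.489 above the control mean, against -0.247 to -0.081 in the other controls and 0.252 to 0.912 in resected arrays. Without that array 23 macrophage genes rose and 1 fell. Camera gave an adjusted p = 1.05e-08, and an adjusted p = 0.317 with an estimated correlation. Of the 4 calls, that of ncf1 alone held with each array left out in turn: spi1b lost its call without any 1 array but control replicate 2 (adjusted p = 0.0514 to 0.111), csf1ra without resected replicate 2 or 3 (0.0624 and 0.0592), and cxcr4b without resected replicate 3 (0.0518).

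Of 13 neutrophil genes, the protease mmp9 (0.86 ± 0.14) and the leukotriene pathway gene alox5ap (0.81 ± 0.14) rose, of which mmp9 is also in the matrix list, and 0 fell (5 and 0 adjusted over the list alone; 4 and 0 over all genes without control replicate 2, whose mean over the members was 0.234 above the control mean, against -0.214 to 0.029 in the other controls). By camera the adjusted p was 0.00395, and the adjusted p was 0.232 with an estimated correlation. Of 64 genes of inflammation and cytokine signalling, 7 rose and 2 fell (16 and 6 adjusted over the list alone; 16 and 4 over all genes without control replicate 2). The chemokines cxcl12a (1.53 ± 0.24) and cxcl12b (1.09 ± 0.19) and the complement genes c4b (1.47 ± 0.22) and c6.2 (1.13 ± 0.15) led the increases. The members that fell, named after their values were seen, were cebpd (-0.89 ± 0.18) and pim1 (-0.54 ± 0.13). The call for cebpd ended without control replicate 4 or resected replicate 2 (adjusted p = 0.0586 and 0.057), and that for pim1 without any 1 array but control replicate 2 (0.0593 to 0.0882). With camera the list had an adjusted p = 0.00395, and an adjusted p = 0.317 with an estimated correlation. Of 14 lymphocyte genes limma called 0 changed, and 0 adjusted over the list alone, with 3 higher and 1 lower at an unadjusted p under 0.05. The smallest p were those of cd28 (0.30 ± 0.09, adjusted p = 0.0851, limma) and gata3 (-0.36 ± 0.12, adjusted p = 0.11), and camera gave an adjusted p = 0.381.

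**Figure D3:**
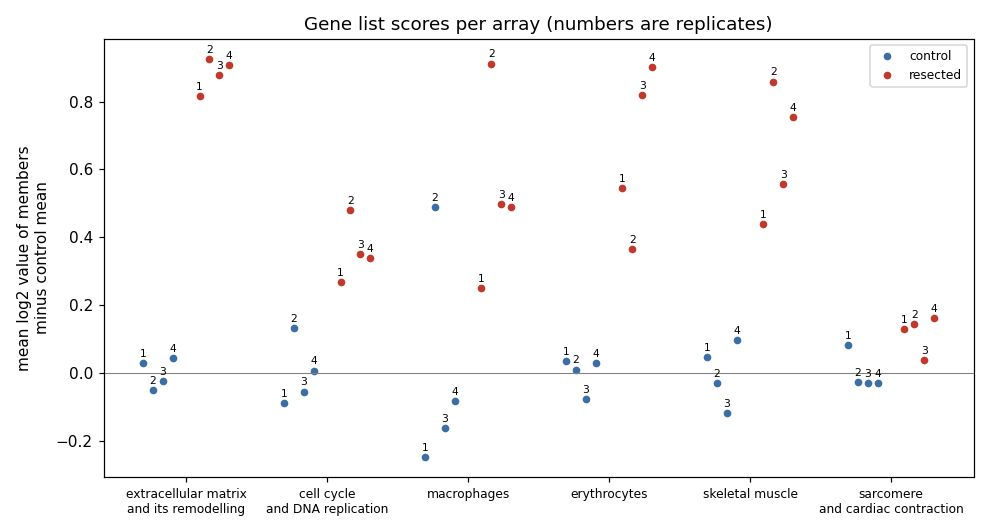
Mean log2 value of the members of 6 gene lists on each array, after the mean of the 4 control arrays was subtracted from each gene; numbers mark the replicates. Resected arrays lie at 0.816 to 0.926 for the extracellular matrix list, and control replicate 2 lies at 0.489 for the macrophage list but at -0.05 for the matrix list.

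The list for the contractile apparatus of heart muscle was not called. Of 32 sarcomere genes 6 rose and 0 fell (8 and 0 adjusted over the list alone): the largest changes were in tpm1 (0.86 ± 0.15), actn2b (0.85 ± 0.10), myh7 (0.83 ± 0.11) and xirp2a (0.73 ± 0.17). The list median was -0.02 and its mean 0.12, and camera gave an adjusted p = 0.122 (0.0476 without control replicate 1 and 0.0394 without resected replicate 3). Markers of fast skeletal muscle, the muscle type of the body wall, rose for 11 of 25 genes and fell for 0 (12 and 1 adjusted over the list alone). The parvalbumins pvalb2 and pvalb1 (1.70 ± 0.17), the troponin tnnc2.2 (1.85 ± 0.21) and the myosin light chain mylz3 (1.80 ± 0.16) led them. In resected ventricles pvalb2 was at 8.81 ± 0.42 and mylz3 at 7.97 ± 0.38 (SD, n = 4). For this list the adjusted p of camera was 1.62e-07, and the adjusted p was 0.193 with an estimated correlation. The call for xirp2a ended without control replicate 3 or 4 or resected replicate 1, 3 or 4 (adjusted p = 0.0596 to 0.082).

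Of 99 genes of mitochondrial energy metabolism, the cytochrome oxidase subunits cox6a1 (0.90 ± 0.10) and cox6b1 (0.62 ± 0.12) rose and slc25a4 fell, with 2 and 1 adjusted over the list alone. Camera gave an adjusted p = 0.365, and 0.0153 without control replicate 2, in the lower direction both times; without control replicate 3 the direction turned (0.353). Of 32 glycolysis genes, 5 rose and 1 fell (8 and 2 adjusted over the list alone). The regulatory enzyme pfkfb3 rose by 2.12 ± 0.27 and gapdhs by 0.82 ± 0.14, while gpib fell (-0.71 ± 0.15). For glycolysis camera gave an adjusted p = 0.0164, an adjusted p = 0.395 with an estimated correlation and 0.0719 without control replicate 2. The call for gpib ended without control replicate 3 or 4 (adjusted p = 0.0546 and 0.0661).

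Stress genes went both ways: of 54 heat shock, chaperone and oxidative stress genes, 6 rose and 4 fell (13 and 6 adjusted over the list alone). The increases were led by egln3 and the thioredoxin txnb (1.63 ± 0.37). The mitophagy receptor bnip3 (-1.03 ± 0.14) and the hypoxia-inducible factor gene epas1a (-0.60 ± 0.12) fell, as did sqstm1 (-0.48 ± 0.09) and gpx4a (-0.43 ± 0.10), named after their values were seen. Without control replicate 2, 15 rose and 4 fell. By camera the adjusted p was 0.0131, an adjusted p = 0.395 with an estimated correlation and 0.0837 without control replicate 4. The call for txnb ended without any 1 array but control replicate 2 (adjusted p = 0.0512 to 0.0933), and that for gpx4a without control replicate 3 or 4 or resected replicate 2, 3 or 4 (0.072 to 0.104).

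Of 100 genes of growth factor and developmental signalling, 12 rose and 4 fell (13 and 6 adjusted over the list alone), and the list was not called (median -0.02, mean 0.08; camera adjusted p = 0.189, higher). The increases included mdka, aldh1a2 and the matricellular gene ccn2a (0.85 ± 0.20). The decreases were in her9 (-0.95 ± 0.20) and, named after their values were seen, fgf3 (-0.61 ± 0.13), erbb2 (-0.58 ± 0.10) and spry2 (-0.33 ± 0.07). The call for ccn2a ended without control replicate 1 or 3 or resected replicate 1, 2 or 3 (adjusted p = 0.0549 to 0.104), and that for her9 without any 1 array but control replicate 2 and resected replicate 3 (0.0508 to 0.0658). The call for fgf3 ended without control replicate 4 or resected replicate 2 or 3 (0.0611 to 0.0651), and that for spry2 without control replicate 3 or resected replicate 1, 2 or 3 (0.0581 to 0.082). Among 22 cardiac transcription factors, prrx1a (1.04 ± 0.14) and mef2ca (0.44 ± 0.10) rose and nkx2.5 fell (-0.36 ± 0.09), with 3 and 2 adjusted over the list alone. With camera the list had an adjusted p = 0.954 in the higher direction, beside a median of -0.05 and a mean of 0.01. The call for nkx2.5 ended without any 1 array (0.0615 to 0.118), with an intensity trend in the variance prior (0.0708), with array weights (0.0593) and with median centring (0.0511), and that for mef2ca without any but control replicate 2 (0.0519 to 0.0823).

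Of the 7 measured members of polycomb repressive complex 2, which methylates histone H3, the histone-binding protein rbbp4 rose (0.66 ± 0.12, adjusted p = 0.0111, limma) and the core subunit eed fell (-0.33 ± 0.08, adjusted p = 0.0396), with 2 and 1 adjusted over the list alone. The catalytic subunit ezh2 was at 0.41 ± 0.12 (adjusted p = 0.0733, limma), suz12a at 0.13 ± 0.08, suz12b at -0.02 ± 0.13, rbbp7 at 0.11 ± 0.10 and aebp2 at -0.04 ± 0.11. For this list the adjusted p of camera was 0.239, and the call for eed ended without any 1 array but control replicate 2 (adjusted p = 0.0506 to 0.102) and with an intensity trend in the variance prior (0.0678). Of 13 genes on the list of microRNA biogenesis and action, 12 did not pass and 0 rose. The 1 that fell was ctdspla, a phosphatase gene (-0.63 ± 0.15). Adjusted over the list alone 2 were lower and 0 higher, and camera gave an adjusted p = 0.143. The call for ctdspla ended without control replicate 3 or 4 or resected replicate 1 or 2 (0.0552 to 0.0862). Among 70 ribosomal protein genes, rpl22l1 (0.54 ± 0.10) and rps27l (0.64 ± 0.15) rose and 0 fell (1 and 0 adjusted over the list alone). Camera gave an adjusted p = 0.587 in the higher direction, beside a median of -0.02 and a mean of 0.01. The call for rps27l ended without control replicate 1 or 4 or resected replicate 2 or 3 (0.0695 to 0.101).

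Of 27 liver genes, the transferrin tfa (2.15 ± 0.16) and the haptoglobin hp (0.96 ± 0.20) rose and hpxb fell (-0.43 ± 0.09). Adjusted over the list alone 2 rose and 4 fell, and camera gave an adjusted p = 0.137. The level of hpxb was low, at 3.35 in control and 2.92 in resected arrays, where the array medians lay between 5.78 and 5.82. Of 28 epithelial and gill genes, krt4 (0.92 ± 0.12) and dspa (0.43 ± 0.09) rose and krt91 fell (-0.98 ± 0.26). Adjusted over the list alone 2 rose and 1 fell, and camera gave an adjusted p = 0.217 (0.0394 without resected replicate 3). The probe set of krt91 ends in _x_at. Of 21 genes of neurons and Schwann cells, syt1a fell and 0 rose (1 lower and 0 higher adjusted over the list alone; camera adjusted p = 0.326). Among 5 atrial genes limma called 0 changed, and 0 adjusted over the list alone, with 1 higher and 0 lower at an unadjusted p under 0.05 (camera adjusted p = 0.712), with s1pr1 at 0.32 ± 0.13 (adjusted p = 0.169, limma) and nr2f2 at -0.25 ± 0.15. The calls for hp and hpxb ended without control replicate 4 or resected replicate 2 (adjusted p = 0.0586 to 0.0656), that for dspa without resected replicate 1 or 2 (0.0514 and 0.0691) and with the mean of its probe sets (0.105), and that for krt91 without any 1 array but control replicate 2 (0.0681 to 0.144).

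With the preset correlation camera called 12 of the 25 lists, all higher in resected ventricles, and with an estimated correlation 1, extracellular matrix. For 3 of the 12, extracellular matrix, cell cycle, and smooth muscle and outflow tract, none of the other divisions of the 8 arrays into groups of 4 gave as small a p, and for the other 9 at least 1 did. With fry, which asks whether the members move one way and does not set them against other genes, the calls of 4 ended: glycolysis and macrophages (adjusted p = 0.068 each), inflammation (0.104) and stress genes (0.149). Without the dimmest 50% of probe sets those of glycolysis and stress genes (0.0814 each), neutrophils (0.0619) and thrombocytes (0.0637) ended.

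The arrays separated by group. The first principal component held 47% of the variance and placed the resected arrays at 14.3 to 26 and the control arrays at -24.1 to -8.5. Control replicate 2, at -8.5, lay nearest the resected arrays. The second component held 15.4% and set control replicates 1 and 2 (20.1 and 11.4) against control replicates 3 and 4 (-21 and -6.9). On it the resected arrays lay at -5.2 to 3.1. The mean Pearson correlation across probe sets was 0.9938 within resected arrays, 0.9892 within control arrays and 0.9834 between groups, and 0 pairs of arrays were identical. The 3' minus 5' difference of the actin and GAPDH control transcripts was -0.62 ± 0.09 in control and -0.37 ± 0.11 in resected arrays (SD, n = 4; exact permutation p = 0.0286, the smallest that 4 against 4 allows). For the actin transcript alone the difference between groups was 0.542 (exact permutation p = 0.0286), and for GAPDH alone -0.0251 (exact permutation p = 0.771). The actin transcript is acta1, and it was its 3' probe set that rose (0.5, against 0.1 for the middle and -0.05 for the 5' probe set). The group difference thus rests on 1 probe set, so a change in expression cannot be told apart from RNA quality.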

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

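The tests of the 3 patterns weighed here were chosen only after the results were seen. An array was picked out when its gap to the nearest array of its group was a large part of the group's range. Of 266 groups of 4 values tested, 15 had such an array, and in simulated normal values 5.2% of groups did. The values of one array over many genes are not independent, so these numbers do not show an excess.

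Control replicate 2 lay at -8.5 on the first principal component, against -24.1 to -22.3 in the other control arrays. It also stood apart for the myeloid transcription factor spi1b, at 7.5 against 6.6 to 6.73, and for rbbp4, at 8.86 against 8.37 to 8.43. Among control arrays, replicate 3 was picked out for anxa2a (10.76 against 10.44 to 10.46) and suz12a (4.86 against 5.04 to 5.07). Control replicate 4 was picked out for actn2b (10.65 against 10.92 to 10.96), apnl (3.22 against 2.81 to 2.87), mylka (6.15 against 6.42 to 6.45) and pvalb1 (6.42 against 6.04 to 6.08). Control replicate 1 stood apart in the mean over the sarcomere list (0.08 against -0.03 to -0.02) and over the epicardium list (-0.05 against 0.01 to 0.02). Among resected arrays, replicate 1 was low for csf1ra (5.52 against 5.92 to 5.95), replicate 2 high for krt18a.1 (10.86 against 10.49 to 10.52) and replicate 3 low for rbbp7 (8.26 against 8.43 to 8.44). Resected replicate 3 was also low in the mean over the epicardium list (0.26 against 0.33 to 0.35).

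Among the manufacturer's control probe sets, which no comparison of the report uses for expression, 4 were higher in resected ventricles by limma. The 3' probe set of actin was higher by 0.5 (adjusted p = 0.00554), and the 3', middle and 5' probe sets of GAPDH by 0.93, 0.95 and 0.96 (adjusted p = 7.96e-05, 7.96e-05 and 0.000159).

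The first pattern weighed was the place of control replicate 2 nearest the resected arrays. A resected pool under a control label would carry the matrix transcripts, yet the 28 matrix genes that rose without that array had a median position of -0.07 in it, on a scale from 0 (control) to 1 (resected), where the other controls reached 0.08. The same genes argue against a pool mixed in part from resected ventricles: their median share on the linear scale was -0.04 (other controls up to 0.04), against 0.97 for 23 macrophage genes, although over all 1083 genes called without that array it sat at 0.47 on the 0 to 1 scale (other controls -0.22 to -0.11). Its 3' minus 5' difference of -0.72 lay below the other controls (up to -0.52) and away from the resected arrays. That index differs between groups through the actin transcript, however. For GAPDH alone the array lay at 0.86, within both the other controls (0.77 to 1.07) and the resected arrays (0.8 to 1.05). The index therefore cannot decide on RNA quality. A higher content of leukocytes in that pool stays open, and no biological explanation was tested, since the design gives none within a group.

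The second pattern was the higher level of skeletal muscle genes in resected ventricles, 9 of the 25 being above the array median in control ventricles. The 11 called members ranked the 4 resected arrays alike (Kendall's W = 0.77, against a median of 0.21 and a 95th percentile of 0.46 in random sets of as many genes called higher), and pvalb2 lay at 8.26 to 9.18 in these arrays against 6.44 to 6.56 in controls, which is consistent with skeletal muscle tissue in all resected pools in differing amounts. For the 5 myosin light chains and troponins with a cardiac counterpart on the array, the pair with the smallest gap differed by 1.56 ± 0.3 (SE) in log2 change. For these 5 that argues against signal from cardiac paralogs. In contrast, actn3b rose less than the cardiac alpha-actinin actn2b (difference -0.34 ± 0.16) and may carry its signal. The rise of pvalb1 and pvalb2 exceeded that of tpm1, the highest of 12 measured genes taken as cardiac (by 0.85 ± 0.22 or more). Whether skeletal muscle also expresses any of the 12, such as tpma or actc1b, was not tested. None of these 12 is a parvalbumin, so this comparison does not bear on signal from paralogs of pvalb1 and pvalb2. For pvalb3, pvalb4 and tnni2b.1 signal from paralogs cannot be told apart either, because the 12 hold no parvalbumin and no troponin I. Of the 12, 4 rose (up to 0.86 for tpm1, median of all 0.17), and the smallest change among pvalb3, pvalb4 and tnni2b.1 was 0.49. Genes regulated together would rank the arrays alike too, so an effect of the resection within the ventricle stays open and untested.

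The third pattern was the higher level of erythrocyte genes, 17 of the 24 being above the array median in control ventricles. The 9 called members ranked the 4 resected arrays alike (Kendall's W = 0.81, against a median of 0.22 and a 95th percentile of 0.52 in random sets), and alas2 lay at 9.35 to 10.74 in these arrays against 7.4 to 7.88 in controls, which is consistent with more blood in the resected pools, in differing amounts. Signal shared between globin paralogs cannot account for the pattern, since 7 of the 9 called members were not globins. Genes regulated together would rank the arrays alike too, so a change of expression within the cells stays open beside blood left by the operation.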

How the results depend on the processing

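All alternatives reported here were planned. Each changed 1 choice, except that the robust variance prior was set together with the trend and the lists were then ranked on the statistics of that fit. With it krt91 and txnb lost their calls (adjusted p = 0.0639 and 0.0701), as did eed and nkx2.5 (0.0691 and 0.069). Of 97 named genes past the threshold, 67 stayed past it with each array left out in turn, 83 under every other setting except no moderation of the variance, and 31 under every other setting. Under the other settings, 85 of 1182 values of named genes lost their call and 0 turned. The cause was not tested for any change given here, except that a left-out array lowers the number of samples. Signal over background could not be assessed from these values, so it is not known which dim probe sets are limited by it.

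With a 2-fold change also required 215 probe sets passed, and with an adjusted p under 0.01, 382. Without moderation of the variance 299 probe sets passed (224 higher, 75 lower) and 201 genes, and 64 of the named genes lost their call, gata2a among them (0.117). Whether the replicate numbers pair the arrays is not settled. The correlation of same-numbered deviations was 0.12, 0.14, -0.01 and -0.16 for replicates 1 to 4. In both groups replicates 1 and 2 correlated best with their own number, and replicates 3 and 4 did not. With the replicate block 1026 probe sets passed (714 higher, 312 lower) and 689 genes, 548 of them among the 708. Of the named genes, 10 were then not called: ccn2a (adjusted p = 0.0594), eed (0.0664), fgf3 (0.052), gata2a (0.0542), gpx4a (0.0675), mef2ca (0.0523), mylka (0.0552), nkx2.5 (0.0882), pfkpa (0.0611) and spry2 (0.0746).

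With an estimated correlation camera called 1 list. For smooth muscle (-0.05) and epicardium (-0.02) that correlation lay below the preset 0.01, so a higher correlation did not end their calls. The adjusted p was 0.193 for cell cycle, epicardium and skeletal muscle, 0.182 for smooth muscle, 0.232 for erythrocytes, neutrophils and thrombocytes, 0.317 for inflammation and macrophages, and 0.395 for glycolysis and heat shock. With fry it was 0.068 for glycolysis and macrophages, 0.104 for inflammation and 0.149 for heat shock, and the direction turned for cardiac transcription factors (0.943) and endothelium (0.79). With the lowest 30% of probe sets left out the direction turned for cardiac transcription factors (0.927) and endothelium (0.616). With the lowest 50% left out it turned for cardiac transcription factors (0.901), endothelium (0.734) and liver (0.538), and calls ended for glycolysis and heat shock (0.0814 each), neutrophils (0.0619) and thrombocytes (0.0637). Under the replicate block endothelium turned (0.999). Without the lowest 50% the mean correlation of arrays was 0.9739 within control, 0.9864 within resected and 0.9579 between groups. The 3' minus 5' difference between groups turned to -0.0251 with GAPDH alone.

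With 1 array left out in turn, 545 to 1608 probe sets passed (394 to 951 higher, 151 to 657 lower) and 371 to 1083 genes. The lowest counts came without resected replicate 2 and the highest without control replicate 2. Camera's adjusted p ranged from 0.00295 to 0.0719 for glycolysis, 0.00121 to 0.0837 for heat shock and 0.0119 to 0.0593 for thrombocytes, lists whose calls could end. It ranged from 0.0394 to 0.196 for sarcomere, 0.0394 to 0.684 for epithelium and 0.0153 to 0.839 for mitochondrial metabolism, lists that could gain a call. Lists whose direction turned were atrial cardiomyocytes (0.442 to 0.94), cardiac transcription factors (0.615 to 0.987), endothelium (0.627 to 0.975), ribosomal proteins (0.317 to 0.828) and mitochondrial metabolism. Of the named genes, the log2 change turned for aebp2 (-0.12 to 0.04), bmp4 (-0.08 to 0.13), itga2b (-0.14 to 0.15), smtnb (-0.3 to 0.05), acta2 (-0.2 to 0.04), fli1 (-0.15 to 0.03) and suz12b (-0.14 to 0.05), none of which passed the threshold.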

Other observations

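The lists of autophagy and ribosome biogenesis genes were chosen only after values were seen, and the test of autophagy members was set before those members' values were seen. Several genes of autophagy were lower in resected ventricles. Of 30 measured genes of a list of autophagy and muscle atrophy written after the first results, 6 fell and 0 rose by limma: the kinase gene ulk1b (-1.42 ± 0.31), the mitophagy receptors bnip3 (-1.03 ± 0.14) and bnip4 (-0.95 ± 0.16), the phosphoinositide 3-kinase regulator pik3ip1 (-0.96 ± 0.19), atg101 (-0.50 ± 0.10) and sqstm1 (-0.48 ± 0.09). The call for ulk1b was lost without control replicate 3 or resected replicate 1 or 3 (limma adjusted p = 0.0517 to 0.0621), and that for atg101 without resected replicate 3 (0.0515). The hypothesis of a general fall of autophagy transcripts was tested on the 12 members whose values had not been seen, for which limma's camera gave an unadjusted p of 0.134 with a median of -0.08 ± 0.31 (SD over genes). Of these 12, 10 lay below 0, where the median over all 8793 genes was also below 0 (-0.0441). The bound set beforehand, a median above -0.2, made no allowance for this spread, and the 12 leave out 4 of the 6 genes that fell, so a general fall is neither shown nor excluded.

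Genes of ribosome assembly in the nucleolus gave a like picture. Of 62 measured genes, 12 fell and 0 rose, with ddx52 at -1.35 ± 0.18, sdad1 at -1.05 ± 0.18, nob1 at -1.02 ± 0.19 and ddx54 at -0.98 ± 0.14 (SE, n = 4 arrays per group; limma). Of the 62, 39 lay below 0, and the median was -0.09, beside a median of -0.0441 over all 8793 genes. Whether these transcripts fell as a group was not tested. These genes were chosen after their values were seen.

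The 8 arrays can be divided into groups of 4 in 35 ways. The 1062 changed probe sets were matched by 1 of these, the real one, and the highest of the others gave 1. For the 708 changed genes, counted from the same fit, the highest other gave 0, with 1 split as extreme. These counts argue against chance, at the smallest share that 35 splits allow, and cannot exclude it. The number of lists called does not argue against it: 2 of 35 splits gave 12 or more, and the highest other gave 14. That split set control replicate 1 with resected replicates 1, 2 and 4. It is 1 of 16 that set 3 arrays of a group with 1 of the other and so keep part of the real contrast (median 9 lists), while the 18 splits that mixed the groups evenly gave at most 7. For single lists, the exact count over all 35 splits was 1, the real one, for extracellular matrix (camera p = 3.19e-26, smallest other 1.17e-13), cell cycle (2.13e-15, 1.14e-14) and smooth muscle (0.00109, 0.0116). Each count is the smallest possible. Over 25 lists, however, 0.714 would be led by the real split by chance. Camera's p also has no like footing across splits, as set out below. The counts therefore cannot decide on chance for these lists. The calls for cell cycle and smooth muscle ended with an estimated correlation (camera adjusted p = 0.193 and 0.182). With fry they held (adjusted p = 0.00781 and 0.000255). For smooth muscle that correlation was -0.05, below the preset 0.01, so a higher correlation did not end its call. For cell cycle it was 0.19. The call for extracellular matrix held with camera's estimated correlation and with fry (adjusted p = 0.00322 and 4.35e-06).

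For the other 9 called lists the count of splits does not exclude chance, nor can it decide the question. Camera sets the members against all other genes, of which 708 changed in the real split and 0 in any other. Its p therefore has no like footing across splits. As small a p came from 2 splits for epicardium (0.00569, smallest other 0.0014), 3 for skeletal muscle (2.99e-08, 1.38e-08) and thrombocytes (0.00908, 0.00419), 4 for erythrocytes (3.25e-08, 1.46e-10), 5 for glycolysis (0.00723, 3.53e-07), 6 for neutrophils (0.00126, 0.000265), 7 for macrophages (1.26e-09, 1.84e-21), 8 for inflammation (0.00112, 2.89e-07) and 10 for heat shock (0.00471, 4.5e-05). The count does not exclude chance either for the lists that were not called. Their splits numbered 6 for sarcomere (0.0634, 0.00207), 7 for growth factors (0.121, 0.0156), 10 for polycomb (0.172, 0.0541), 11 for microRNA (0.0858, 0.00398), 13 for liver (0.0768, 0.000482), 20 for lymphocytes (0.32, 0.000719) and epithelium (0.147, 6.36e-06), and 21 for neurons (0.248, 0.000131). They numbered 28 for mitochondrial metabolism (0.292, 5.1e-23), 30 for ribosomal proteins (0.517, 3.05e-07), 33 for atrial cardiomyocytes (0.655, 0.00107), 34 for endothelium (0.926, 0.0123) and 35 for cardiac transcription factors (0.954, 9e-05). For epicardium, skeletal muscle, thrombocytes, erythrocytes and glycolysis, the other splits with as small a p all kept 3 arrays of a group together, while for neutrophils, macrophages, inflammation and heat shock 1, 2, 3 and 3 of them mixed the groups evenly. The mean over the members leaves other genes out. It was higher in every resected array than in any control array for erythrocytes (0.365 to 0.901 against -0.077 to 0.035) and skeletal muscle (0.44 to 0.859 against -0.118 to 0.098). The same was true of epicardium, thrombocytes and neutrophils, and of extracellular matrix. It was also true of cell cycle (0.269 to 0.48 against -0.087 to 0.133) and smooth muscle (0.339 to 0.469 against -0.054 to 0.047). For macrophages, glycolysis, inflammation and heat shock the groups overlapped, and no test was run on these means.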
